A study of Caenorhabditis elegans with 6 samples.

How the data were processed

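The samples were whole wild-type worms raised on Cry5B-producing or control bacteria, 3 arrays per group, each hybridised with fragmented, biotin-labelled cDNA from 100 ng of total RNA, per the labels' protocols. Groups and replicate numbers were taken from the labels. The deposited table holds values on the log2 scale, which per the submitters' processing notes were made with RMA in Affymetrix Expression Console, with Transcriptome Analysis Console also named. RMA subtracts background, forces the same distribution on every array by quantile normalization and summarises the probes of a probe set by median polish, so it hides any change in total RNA and sets changes relative to the bulk of probe sets. Tool versions, the annotation that the authors used and the settings of any test by them are not given in the sources used here. The log2 unit was read from the values, which ran from 0.71 to 13.83 with near-equal distributions on the 6 arrays. Arrays have no read depth, and their number limits the precision.

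Probe sets were named through the platform annotation supplied with the series: 25546 of 28387 probe sets had 1 gene symbol, 646 had several and were not named, and 2195 were not listed there and are unnamed here. Of the 1-symbol probe sets 25495 matched the RefSeq gene table of assembly WBcel235, 51 did not, and 0 symbols changed; the table served for names and gene types only, and no coordinates are given. Of 25478 genes, 57 had more than 1 probe set and were represented by the one with the highest mean over all arrays. The planned removal of control probe sets was not made, because no column used here marks them, so all probe sets entered the fit. The gene ifa-2 was found under its current name mua-6. Listed names with no probe set of their own, such as hif-1 and the hsp-16 genes other than hsp-16.2 and hsp-16.41, were not read as single genes. Of the 7 such names in the heat shock list, 6 lay on probe sets of several genes, which entered the fit unnamed.

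The 3 Cry5B arrays were compared with the 3 control arrays by limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust fitting, two-sided), with Benjamini-Hochberg adjustment over all 28387 probe sets and a threshold of 0.05. This gave 3533 called probe sets, 2245 higher and 1288 lower. An adjusted p in the text is limma's unless camera is named. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, so none was used for single genes. Gene lists were tested with limma's camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over 30 lists). The lists, the designs, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered intermediate filaments, the intestinal terminal web, toxin defence, C-type lectins, lysozymes and relatives, epidermal antimicrobial peptides, infection response genes, the intracellular pathogen response, heat shock, the unfolded protein response, xenobiotic and antioxidant enzymes, hypoxia, autophagy, fasting and lipids, ribosomal proteins, sperm, oocytes, germ cells, vitellogenins, early embryos, cuticle, moulting, intestine, muscle, pharynx, neurons and epidermis. At most 2 genes of any list were shared with another list.

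The genes named by rule were the 6 called genes with the largest rises and the 6 with the largest falls (named symbols, groups not overlapping, at most 1 per symbol stem), every intermediate filament gene, the 2 called members of each other list with the largest change or, where fewer than 2 were called, the 2 with the smallest p, and ifo-1, sma-5, bbln-1, act-5, pmk-1, kgb-1, hsp-4 and ttm-2. Others are marked as named after their values were seen.

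Alternatives were cyclic loess on top of RMA, centring on ribosomal protein genes or on muscle and neuron markers, leaving out the dimmest 25% of probe sets, trend and robust moderation, no moderation, array weights, a fold of at least 2, the mean over a gene's probe sets, the replicate number as a block, each array left out in turn, and for lists an estimated correlation and a background without stage genes. Restricting the fit to listed probe sets, leaving out both arrays numbered 2 and levelling on the deviations of muscle and neuron markers from their own means were chosen after seeing the data. The fit was tested on simulated data for this comparison, with the arrays' own means and spread and 200 of 28387 probe sets changed: it recovered 20% of 100 changes of 1 on the log2 scale and 80% of 100 changes of 2, and called 4 of 28187 unchanged probe sets. In simulated lists the 1 shifted list was called and 0 of the others. The 200 changed probe sets were far fewer than the 3533 called in the data. With fewer changes the adjusted threshold is stricter, so the shares recovered do not give the sensitivity in the data. The simulated probe sets were drawn independently of each other, with no array standing apart. The simulation therefore does not test camera on lists with correlated members, and the germ cell list had an estimated correlation of 0.83. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 joined the tables and drew the figures. No 2 arrays held the same values, with at most 4.54% of probe sets identical between a pair.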

Results

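Whole Caenorhabditis elegans of the wild-type strain N2 were profiled on Affymetrix expression arrays after 4 days at 18 °C on bacterial lawns. The lawn was Escherichia coli JM103 that made Cry5B, a crystal protein of Bacillus thuringiensis that forms pores in intestinal cells, or control JM103 without the toxin. Each group had 3 arrays, from independent RNA isolates. The age label reads L3 for every Cry5B array and adult for every control array, whereas the treatment protocol states L4 or young adult for the worms collected. Toxin and labelled stage coincided on all 6 arrays and cannot be told apart in any comparison here. The table held 28387 probe sets with RMA values on the log2 scale, from 0.71 to 13.83, and array medians lay between 4.75 and 4.92. Over all probe sets, arrays of the same group correlated at r = 0.987 to 0.995 for Cry5B and 0.971 to 0.990 for control, against 0.940 to 0.955 between groups (across probe sets, which are not independent replicates). Control replicate 2 lay apart from the other control arrays, at r = 0.973 and 0.971, and the second principal component, with 18.1% of the variance, separated it from them (-69.0 against 28.8 and 33.4). The median SD of a probe set was 0.169 in the Cry5B group and 0.264 in the control group. The number of arrays limits the precision of every value below.

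The series compared worms raised on Cry5B with worms raised on control bacteria, and its title concerns the intermediate filaments of the intestine under attack by microbes and toxins. In Cry5B worms 48 of 167 cuticle collagens, 28 of 46 sperm genes and 23 of 34 infection response genes rose, and 16 of 52 early embryo genes and 2 of 5 vitellogenins fell. With 1 array left out the embryo falls numbered from 1 to 35 and both vitellogenin calls ended in 4 of the 6 fits. In turn, muscle and neuron centring, which overshoots as described below, ended the falls of both lists. Levelling on the same genes, a smaller shift, left 6 embryo falls and no vitellogenin fall, with medians of -0.44 and -0.59. Of the 5 lists, camera with an estimated inter-gene correlation called the infection response genes alone. The gene rol-1, mutations of which make worms roll, rose 138-fold (log2 change 7.11 ± 0.26). Changes are given as Cry5B minus control ± limma's moderated SE, with 3 arrays per group. This SE pools the spread of both groups and draws on that of all probe sets. The collagen col-38 rose 116-fold (6.86 ± 0.37) and the C-type lectin clec-45 88.9-fold (6.47 ± 0.24). The adult cuticle collagen bli-2 measured 6.92 ± 0.30 higher, but from a control mean of 3.01. The sperm peptide gene nspd-1 rose 59.0-fold (5.88 ± 0.61) and the claudin-like gene clc-21 48.7-fold (5.61 ± 0.35). Among falls, clec-190 was 14.6-fold lower (-3.87 ± 0.28) and the collagen col-74 13.1-fold (-3.71 ± 0.49), and pud-4 measured -4.90 ± 0.18, to a Cry5B mean of 3.05. The dimmer means of bli-2 and pud-4 lay under 3.19, the highest lower quartile of the 6 arrays, and are not shown to be above background, so these 2 differences are lower bounds in size if those means are background. Further falls were those of the acid sphingomyelinase gene asm-3, 12.9-fold (-3.69 ± 0.35), the cuticlin gene cut-3, 11.5-fold (-3.53 ± 0.40), and mtre-1, 11-fold (-3.46 ± 0.41). As the naming rule required, each of these 12 genes was called, with all 3 Cry5B arrays on one side of all 3 control arrays. Their limma adjusted p lay between 1.5e-05 and 0.0030, and at most 1 gene per symbol stem was taken in each direction.

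Of 25478 genes with a probe set of their own, 3294 (12.9%) passed limma's moderated test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 2102 were higher and 1192 lower in Cry5B worms, so 63.8% of calls were rises. Large changes were mostly rises: 232 called genes were at least 8-fold higher and 11 at least 8-fold lower. Among protein-coding genes 2001 rose and 1083 fell, and among 5972 noncoding RNA genes 34 rose and 85 fell. Groups did not overlap for 7495 genes, 29.4%, against 10% expected by chance. The split of calls depends on the level taken as unchanged, on the arrays and on the moderation. Centring each array on ribosomal protein genes shifted every change by -0.40 and gave 1297 higher and 3347 lower genes (27.9% rises). Centring on muscle and neuron genes shifted every change by 0.75 and gave 2860 higher and 44 lower (98.5% rises). This centring takes the median of their levels and overshoots: the median change of these genes went from -0.34 to 0.41. Levelling on their deviations from their own means, added after the data were seen, shifted every change by 0.39, left them at 0.058 and gave 2829 and 283 (90.9%). Cyclic loess gave 2275 and 1079 (67.8%), array weights 3683 and 4090, and no variance moderation 992 and 171. The count was 5878 genes without control replicate 2, 3078 higher and 2800 lower. It was 1587 (1305 and 282), 1617 (1335 and 282) and 2014 (1533 and 481) without Cry5B replicate 1, Cry5B replicate 3 and control replicate 3. Leaving out both arrays numbered 2, a setting chosen after seeing the data, gave 6721 genes, 3210 higher and 3511 lower.

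**Figure D1:**
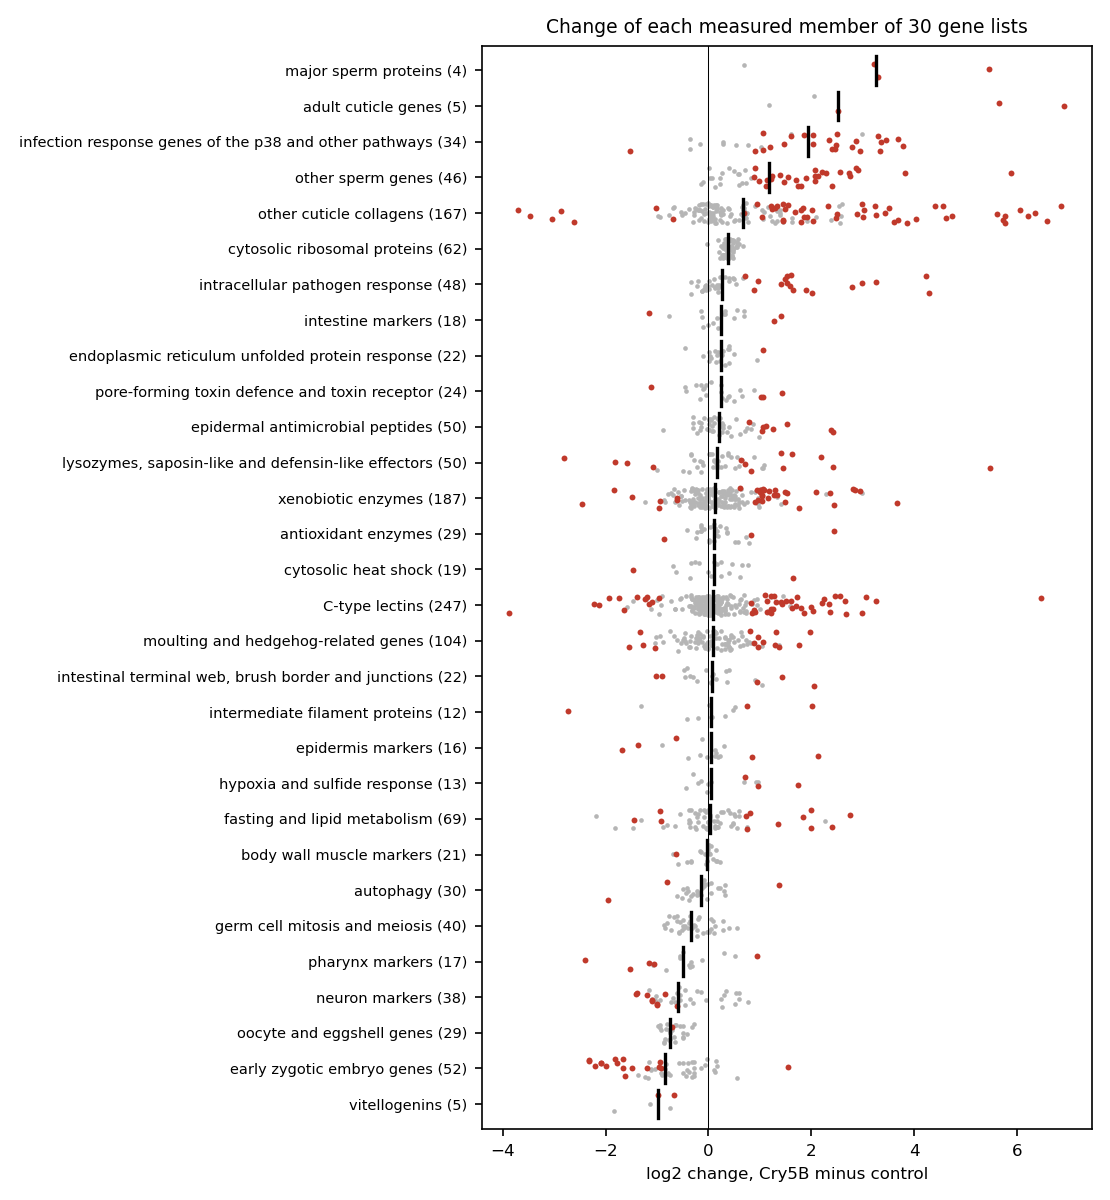
Log2 change (Cry5B minus control, horizontal axis) of each measured member of the 30 gene lists (vertical axis, members measured in brackets), with red points for genes at adjusted p under 0.05, grey points for others and black bars for list medians. Medians run from -0.98 for vitellogenins to 3.26 for major sperm proteins on the deposited scale; centring on ribosomal protein genes moves every point by -0.40 and centring on muscle and neuron genes by 0.75.

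The 30 gene lists were fixed before the data were examined. On limma's camera test, which compares a list with all other genes, 12 lists lay higher and 6 lower in Cry5B worms with a preset inter-gene correlation of 0.01. With an estimated correlation 1 of these 18 calls held, that of the infection response genes. That setting also takes its p from far fewer degrees of freedom, so the lost calls do not measure correlated members alone. The 2 centrings move the changes of all genes alike and keep the differences in change between genes. They can alter the spread between arrays, and camera was not run after them. They turn the sign of many lists' medians, as given for each list below. Muscle and neuron centring turned the negative medians of autophagy, muscle and germ cell genes and, further from 0, of oocyte, neuron and pharynx genes. After the smaller shift by levelling, the oocyte, neuron and pharynx medians were -0.34, -0.19 and -0.097, below 0 as on the deposited scale, and 6 early embryo genes fell. Over all genes the median change was -0.06 on the deposited scale, -0.46 after ribosomal centring and 0.69 after muscle and neuron centring.

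Intermediate filament genes moved in both directions. Of 12 measured, 2 rose, 1 fell and 9 did not pass, over all genes as well as adjusted over the list alone. Among the intestinal filament genes, ifd-2 (probe set 18624603) rose 4.06-fold (2.02 ± 0.30, adjusted p = 0.0051), from 8.21 ± 0.63 (SD) in control to 10.23 ± 0.10 in Cry5B worms. The other intestinal members did not pass: ifc-1 changed by -1.31 ± 0.55 with a control SD of 1.21, ifc-2 by 0.51 ± 0.27, ifd-1 by -0.42 ± 0.40, ifb-2 by 0.33 ± 0.37 and ifp-1 by 0.02 ± 0.31. Outside the intestine, ifa-4 rose 1.68-fold (0.75 ± 0.18, adjusted p = 0.035) and ifa-3 fell 6.64-fold (-2.73 ± 0.37, adjusted p = 0.0034). The values of mua-6 (also called ifa-2), 0.47 ± 0.26, of the nuclear lamin lmn-1, -0.20 ± 0.17, of ifa-1, 0.06 ± 0.24, and of ifb-1, 0.05 ± 0.20, did not pass. The list's median was 0.06 and its mean -0.04, and camera gave a higher direction with adjusted p = 0.527. Ribosomal centring turned the median to -0.35 and gave 1 rise and 2 falls. Without control replicate 2, 8 of 18 intestine markers rose. In that fit both ifb-2 (0.79, adjusted p = 0.013) and ifc-2 (0.81, adjusted p = 0.017) also passed, and camera gave the filament list adjusted p = 0.0413. Camera's direction was lower without control replicate 3, at 0.856. The call of ifa-4 ended without any single array other than control replicate 2 (adjusted p 0.055 to 0.15) and under ribosomal centring, which made ifc-1 pass at -1.72 (adjusted p = 0.0016).

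**Figure D2:**
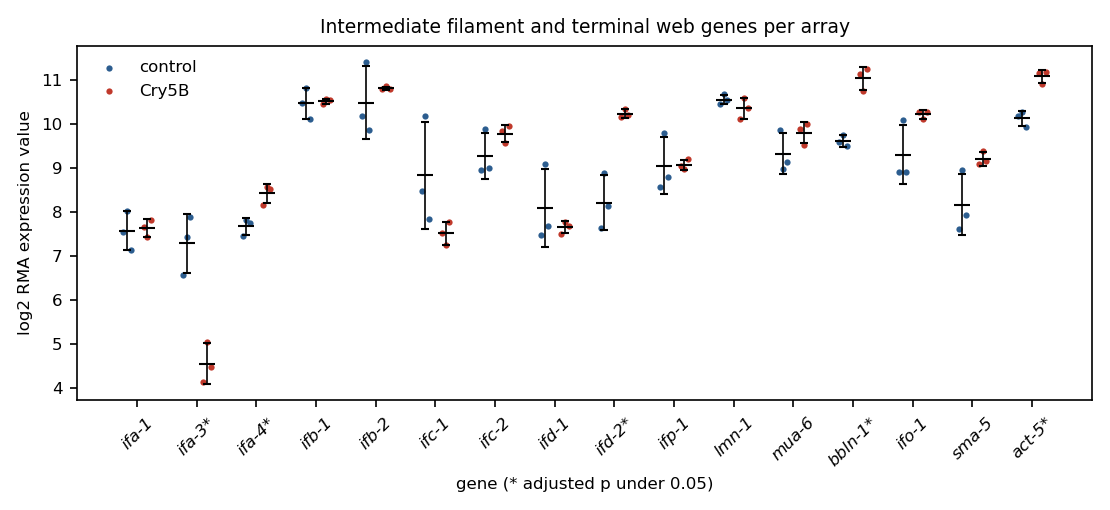
RMA value on the log2 scale (vertical axis) of 12 intermediate filament genes and 4 genes that organise or join the network or the brush border (horizontal axis), with 1 point per array, control in blue and Cry5B in red, and black bars for the mean ± SD of 3 arrays. Red points lie above all blue points for ifd-2, ifa-4, bbln-1 and act-5 and below them for ifa-3 (asterisks, adjusted p under 0.05), and after ribosomal centring ifa-4 and act-5 no longer pass. Red points also lie above all blue points for ifo-1 and sma-5 and below them for ifc-1, which did not pass.

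Genes of the terminal web, brush border and junctions of the intestine also went both ways. Of 22 measured, 3 rose, 2 fell and 17 did not pass, with the same counts adjusted over the list alone. The gene sid-2, for a membrane protein that takes up double-stranded RNA from the gut lumen, rose 4.13-fold (2.05 ± 0.25, adjusted p = 0.0022). A regulator of the filament lattice, bbln-1, rose 2.69-fold (1.43 ± 0.18, adjusted p = 0.0024), and act-5, the actin of intestinal microvilli, 1.94-fold (0.95 ± 0.16, adjusted p = 0.0090). The polarity gene crb-1 (-1.02 ± 0.18) and the E-cadherin gene hmr-1 (-0.91 ± 0.21) fell, both named after their values were seen. The filament organiser ifo-1 had a change of 0.91 ± 0.32 (adjusted p = 0.12) and the kinase gene sma-5, needed for normal intestinal tube form, 1.04 ± 0.33 (adjusted p = 0.091). Camera did not call the list (adjusted p = 0.352), and its median of 0.07 became -0.34 after ribosomal centring, with 2 rises and 2 falls, against 5 and 0 after muscle and neuron centring. Without control replicate 2, where 8 of 18 intestine markers rose, this list had 6 rises. There ifo-1 was at 1.30 (adjusted p = 0.0017) and sma-5 at 1.43 (adjusted p = 0.0033). No member fell without Cry5B replicate 3. The call of act-5 ended without Cry5B replicate 1 or 3 (adjusted p = 0.057 and 0.054) and after ribosomal centring.

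Infection response genes, known targets of the p38 and other immune pathways, rose as a group. Of 34 measured, 23 rose, 1 fell and 10 did not pass (27 and 1 adjusted over the list alone), with a median rise of 3.85-fold (camera adjusted p = 2.97e-16, and adjusted p = 0.0182 with an estimated correlation). The median of 1.95 kept its sign after every scaling, between 1.54 and 2.70. The largest rises were those of dod-20, 13.8-fold (3.79 ± 0.26, adjusted p = 0.00014), and hpo-6, 12.9-fold (3.69 ± 0.16, adjusted p = 3.4e-05), and irg-6 was the member that fell (-1.52 ± 0.23, named after its values were seen). On the same arrays the mean of the sperm genes was 1.40 higher on the log2 scale and that of the early embryo genes changed by -0.84.

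Genes of the intracellular pathogen response, a programme switched on by microsporidia and viruses, rose in 17 of 48 cases, and none fell (18 and 0 adjusted over the list alone). Camera gave adjusted p = 6.51e-07, and adjusted p = 0.251 with an estimated correlation. The median of 0.27 became -0.13 after ribosomal centring, under which 14 members still rose. The largest rises were in pals-37, 19.5-fold (4.28 ± 0.51, adjusted p = 0.0019), and pals-39, 18.9-fold (4.24 ± 0.60, adjusted p = 0.0040). The ubiquitin ligase subunits skr-3, skr-4, skr-5 and cul-6 were also higher, by 2.01 ± 0.28, 2.80 ± 0.21, 3.27 ± 0.44 and 1.53 ± 0.22, and were singled out after their values were seen.

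Among effectors, lysozymes and their relatives rose in 9 and fell in 4 of 50 cases (10 and 4 adjusted over the list alone), with camera adjusted p = 0.0106, and adjusted p = 0.434 with an estimated correlation. The lysozyme gene lys-3 rose 44.3-fold (5.47 ± 0.32, adjusted p = 7.7e-05), and the invertebrate-type lysozyme gene ilys-5 fell 7.03-fold (-2.81 ± 0.41, adjusted p = 0.0046). C-type lectins, a family of carbohydrate-binding domain proteins, rose in 36 and fell in 12 of 247 cases (43 and 15 adjusted over the list alone), with camera adjusted p = 0.00572, and adjusted p = 0.251 with an estimated correlation. Their extremes, clec-45 and clec-190, are given above. Epidermal antimicrobial peptides rose in 8 of 50 cases and fell in 0 (11 and 0 adjusted over the list alone), led by fipr-10, 5.33-fold (2.41 ± 0.40, adjusted p = 0.0082), and nlp-34, 5.22-fold (2.38 ± 0.37, adjusted p = 0.0058). Camera gave this list adjusted p = 0.00113, and adjusted p = 0.251 with an estimated correlation. The medians of these 3 lists, 0.17, 0.09 and 0.20, became -0.24, -0.31 and -0.20 after ribosomal centring. Rises and falls were then 6 and 5, 26 and 23, and 3 and 1, against 14 and 1, 54 and 1, and 12 and 0 after muscle and neuron centring, so the excess of rises in these lists depends on the scaling. The rises numbered 15, 56 and 11 without control replicate 2, and 6, 22 and 3 without Cry5B replicate 3, where fipr-10 had adjusted p = 0.053. Sperm genes were higher and early embryo genes lower on the same arrays, by the means given for the infection response genes.

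The toxin defence list, with the enzymes that build the glycolipid receptor of Cry5B and the p38 and JNK kinases, was not called by camera (adjusted p = 0.0963). Of 24 measured, 3 rose, 1 fell and 20 did not pass, with the same counts adjusted over the list alone. A known target of the p38 kinase under pore-forming toxin, ttm-5, rose 2.68-fold (1.42 ± 0.19, adjusted p = 0.0031). The kinase phosphatase gene vhp-1 (1.06 ± 0.23) and jun-1 (1.03 ± 0.24) also rose, both named after their values were seen. The kinase gene jnk-1 fell 2.17-fold (-1.12 ± 0.27, adjusted p = 0.036). The p38 kinase gene pmk-1 had a change of -0.11 ± 0.22 (adjusted p = 0.80), the JNK-like kinase gene kgb-1 0.62 ± 0.24 (adjusted p = 0.16) and ttm-2 0.88 ± 0.42 (adjusted p = 0.24). The list's median of 0.24 became -0.17 after ribosomal centring, with 1 rise and 1 fall, against 6 and 0 after muscle and neuron centring. With control replicate 2 left out, 8 members rose and 3 fell, and camera gave adjusted p = 0.0144. Both kgb-1 (0.90, adjusted p = 0.0049) and ttm-2 (1.41, adjusted p = 0.0025) then passed. The call of jnk-1 ended without any 1 of the Cry5B arrays or control replicate 3 (adjusted p 0.077 to 0.15) and after muscle and neuron centring.

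Few of the protein folding stress genes with a probe set of their own passed. The genes hsp-16.1, hsp-16.11, hsp-16.48 and hsp-16.49 had none and are not among those counted. In the unfolded protein response of the endoplasmic reticulum 1 of 22 genes rose, the choline kinase gene ckb-2, by 2.1-fold (1.07 ± 0.23, adjusted p = 0.024), and none fell (1 and 0 adjusted over the list alone). Its chaperone gene hsp-4, the BiP homologue, had a change of 0.95 ± 0.26 (adjusted p = 0.057), and passed without control replicate 2 (0.67, adjusted p = 0.034), after cyclic loess and after muscle and neuron centring. Camera called this list higher (adjusted p = 0.00922, and adjusted p = 0.516 with an estimated correlation), and its median of 0.24 became -0.16 after ribosomal centring. Of 19 cytosolic heat shock genes hsp-17 rose 3.13-fold (1.64 ± 0.32, adjusted p = 0.016), hsp-12.1 fell 2.78-fold (-1.48 ± 0.27, adjusted p = 0.013) and 17 did not pass (1 and 1 adjusted over the list alone; camera adjusted p = 0.437), with a median of 0.10 that became -0.30 after ribosomal centring. The calls of ckb-2 and hsp-17 ended without any 1 of the Cry5B arrays or control replicate 3 (adjusted p 0.068 to 0.12 and 0.060 to 0.085). That of hsp-12.1 ended without any 1 of the Cry5B arrays (0.054 to 0.073), and scaling ended those of ckb-2 (ribosomal centring) and hsp-12.1 (muscle and neuron centring).

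Xenobiotic enzymes rose in 27 and fell in 7 of 187 cases (32 and 9 adjusted over the list alone), with the cytochrome P450 gene cyp-13A5 12.7-fold higher (3.67 ± 0.50, adjusted p = 0.0035) and the glutathione transferase gene gst-18 7.76-fold higher (2.96 ± 0.28, adjusted p = 0.00062). Camera gave adjusted p = 0.00234, and adjusted p = 0.430 with an estimated correlation. The median of 0.12 became -0.29 after ribosomal centring, where falls outnumbered rises (13 rises, 20 falls), against 40 and 0 after muscle and neuron centring. Rises numbered 44 without control replicate 2 and 17 without Cry5B replicate 3. Of 29 antioxidant enzymes 2 rose, 1 fell and 26 did not pass (2 and 1 adjusted over the list alone; camera adjusted p = 0.105, and 0.0372 after cyclic loess), and the median of 0.12 became -0.29 after ribosomal centring. The thioredoxin gene trx-3 rose 5.42-fold (2.44 ± 0.32, adjusted p = 0.0028), and trx-1 fell 1.82-fold (-0.87 ± 0.15, adjusted p = 0.0099), a call that ended without Cry5B replicate 1 (adjusted p = 0.053) and after muscle and neuron centring. Of 13 genes of the hypoxia and sulfide response 3 rose and none fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0753, and 0.031 without control replicate 2). The gene cysl-2, for an enzyme of cyanide and sulfide handling, rose 3.36-fold (1.75 ± 0.19, adjusted p = 0.0012) and the prolyl hydroxylase gene phy-2, which modifies collagen, 1.95-fold (0.96 ± 0.16, adjusted p = 0.0085). Ribosomal centring ended the call of phy-2, left 1 rise and turned this list's median from 0.05 to -0.36, and muscle and neuron centring gave 6 rises.

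Autophagy genes rose in 1 and fell in 2 of 30 cases (1 and 2 adjusted over the list alone; camera adjusted p = 0.105). The receptor gene sqst-1, the p62 homologue, rose 2.59-fold (1.37 ± 0.25, adjusted p = 0.012), and epg-2, which serves the removal of germ granule proteins in embryos, fell 3.86-fold (-1.95 ± 0.31, adjusted p = 0.0065). The list's median of -0.14 became 0.61 after muscle and neuron centring, which ended the call of epg-2, and that of sqst-1 ended without Cry5B replicate 1, Cry5B replicate 3 or control replicate 3 (adjusted p 0.057 to 0.069). Genes of fasting and lipid metabolism rose in 9 and fell in 3 of 69 cases (10 and 3 adjusted over the list alone; camera adjusted p = 0.159). They were led by the acyl-CoA synthetase gene acs-18, 6.72-fold higher (2.75 ± 0.17, adjusted p = 9.4e-05), and the acyl-CoA dehydrogenase gene acdh-8, 5.27-fold higher (2.4 ± 0.24, adjusted p = 0.00084). Their median of 0.03 became -0.37 after ribosomal centring, where falls outnumbered rises (7 rises, 10 falls), against 12 and 0 after muscle and neuron centring. Omitting control replicate 2 gave 17 rises and 7 falls, with camera adjusted p = 0.00758. None of 62 cytosolic ribosomal protein genes passed the limma test, over all genes or adjusted over the list alone. As a set they lay 1.30-fold higher by the median (0.38; camera adjusted p = 1.28e-09, and adjusted p = 0.430 with an estimated correlation), a direction that ribosomal centring removes by construction. The smallest p belonged to rpl-38 (0.56 ± 0.15, adjusted p = 0.058) and rpl-14 (0.46 ± 0.13, adjusted p = 0.068), of which rpl-38 passed after cyclic loess and rpl-14 without control replicate 2 (adjusted p = 0.031).

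Sperm genes rose. Of 46 sperm genes other than major sperm proteins, 28 rose, none fell and 18 did not pass (35 and 0 adjusted over the list alone), with a median rise of 2.26-fold (camera adjusted p = 5.4e-20, and adjusted p = 0.139 with an estimated correlation). After nspd-1, the largest rise was that of nspd-7, 14.1-fold (3.81 ± 0.32, adjusted p = 0.00037). Major sperm proteins, the cytoskeletal proteins of nematode sperm, had 4 genes with a probe set of their own, of which 3 rose and none fell (4 and 0 adjusted over the list alone; camera adjusted p = 7.56e-06, and adjusted p = 0.251 with an estimated correlation). Of these msp-78 was 43.6-fold higher (5.45 ± 0.63, adjusted p = 0.0017), and msp-33 was higher (3.30 ± 0.17, adjusted p = 4.8e-05), likewise a lower bound if its control mean of 2.79 is background. A further 26 msp genes lay only on probe sets shared by several genes, and both probe sets shared by msp genes alone were higher, by 4.20 and 4.24. The list medians of 1.18 and 3.26 kept their sign after every scaling (0.77 to 1.93 and 2.86 to 4.01).

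Cuticle collagens rose far more often than they fell. Of 167 collagens outside the adult list, 48 rose, 7 fell and 112 did not pass (61 and 8 adjusted over the list alone), with a median rise of 1.59-fold (camera adjusted p = 2.31e-10, and adjusted p = 0.346 with an estimated correlation). Besides col-38, col-138 was higher (6.59 ± 0.24, adjusted p = 1.5e-05), a lower bound if its control mean of 3.15, not shown to be above background, is background. Of 5 genes of the adult cuticle 3 rose and none fell (5 and 0 adjusted over the list alone; camera adjusted p = 4.64e-06, and adjusted p = 0.251 with an estimated correlation). Besides bli-2, these were bli-1, which like it forms the struts of the adult cuticle, 50.4-fold higher (5.65 ± 0.35, adjusted p = 0.00011), and col-62 (2.52 ± 0.26, named after its values were seen). Both lists kept the sign of their medians after every scaling, 0.67 (0.26 to 1.42) and 2.52 (2.12 to 3.27). Moulting and hedgehog-related genes rose in 10 cases, fell in 4 and did not pass in 90 (12 and 4 adjusted over the list alone; camera adjusted p = 0.141). They were led by the patched-related gene ptr-22, 3.93-fold higher (1.97 ± 0.40, adjusted p = 0.018), and nas-37, a protease that opens the old cuticle, 3.41-fold higher (1.77 ± 0.24, adjusted p = 0.0033). Their median of 0.08 became -0.32 after ribosomal centring, where falls outnumbered rises (4 rises, 12 falls), against 19 and 0 after muscle and neuron centring. The collagens outside the adult list had 51 rises and 12 falls, and 70 and 5, under these centrings. Rises among the collagens outside the adult list numbered 27 without Cry5B replicate 1 and 27 without Cry5B replicate 3. Those among moulting genes numbered 1, 1, 3, 4 and 23 without Cry5B replicate 1, Cry5B replicate 3, control replicate 1, control replicate 3 and control replicate 2. Camera called the moulting list without Cry5B replicate 2 (adjusted p = 0.00931) and without control replicate 2 (0.00844). The gene ptr-22 was not called without Cry5B replicate 1 or 3 or control replicate 1 or 3 (adjusted p 0.063 to 0.080).

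Genes of the early embryo fell. Of 52 early zygotic genes 16 fell, 1 rose and 35 did not pass (27 and 1 adjusted over the list alone), with a median 1.79-fold lower (camera adjusted p = 8.57e-08, and adjusted p = 0.430 with an estimated correlation). The deepest falls were in sdz-28, 5.01-fold (-2.33 ± 0.46, adjusted p = 0.016), and vet-6, 4.98-fold (-2.31 ± 0.44, adjusted p = 0.014), and sdz-35 was the member that rose (1.56 ± 0.20, named after its values were seen). The median of -0.84 stayed below 0 after muscle and neuron centring, at -0.09, but no member then fell, against 30 after ribosomal centring. After levelling on muscle and neuron genes the median was -0.44 and 6 members fell. Of 5 vitellogenin genes, which encode yolk proteins, 2 fell, none rose and 3 did not pass (4 and 0 adjusted over the list alone; camera adjusted p = 0.00627, and adjusted p = 0.430 with an estimated correlation). These were vit-2, 1.98-fold lower (-0.98 ± 0.23, adjusted p = 0.030), and vit-5, 1.59-fold lower (-0.67 ± 0.16, adjusted p = 0.038), and muscle and neuron centring ended both calls and turned vit-5 to 0.08, while ribosomal centring gave 5 falls. The embryo falls numbered 35 without control replicate 2, and 1, 9, 2, 7 and 3 without Cry5B replicates 1, 2 and 3 and control replicates 1 and 3. The calls of sdz-28, vet-6, vit-2 and vit-5 each ended without Cry5B replicate 1 or 3 or control replicate 1 or 3, at adjusted p up to 0.083, 0.077, 0.13 and 0.14. When control replicate 2 was left out, all 5 vitellogenin genes fell. After levelling on muscle and neuron genes the vitellogenin median was -0.59 and none fell.

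Oocyte and eggshell genes lay lower as a set, but 1 of 29 passed, lin-41, a regulator of oocyte growth, 1.63-fold lower (-0.71 ± 0.18, adjusted p = 0.043), and none passed adjusted over the list alone. The list's median was 1.67-fold lower (-0.74; camera adjusted p = 1.12e-06, and adjusted p = 0.526 with an estimated correlation), and puf-5 had a change of -0.84 ± 0.23 (adjusted p = 0.056). None of 40 genes of germ cell mitosis and meiosis passed, over all genes or adjusted over the list alone, with a median of -0.34 (camera adjusted p = 0.0271, and adjusted p = 0.75 with an estimated correlation). The replication helicase genes mcm-5 and mcm-7 had changes of -0.87 ± 0.26 (adjusted p = 0.076) and -0.85 ± 0.28 (adjusted p = 0.10). Control replicate 2 had lower oocyte and embryo genes and higher neuron markers than the other control arrays, as the plot of list means on each array shows. Without it 26 oocyte genes and 11 germ cell genes fell, puf-5, mcm-5 and mcm-7 among them (adjusted p = 0.0038, 0.022 and 0.0029). Without any other single array lin-41 was not called (adjusted p 0.062 to 0.17), and camera did not call the germ cell list without Cry5B replicate 1 or 3 (0.0633 and 0.19) or control replicate 1 or 3 (0.222 and 0.297). After ribosomal centring 22 oocyte genes and 11 germ cell genes fell. After muscle and neuron centring none fell, the medians were 0.01 and 0.41, and lin-41 was at 0.04.

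**Figure D3:**
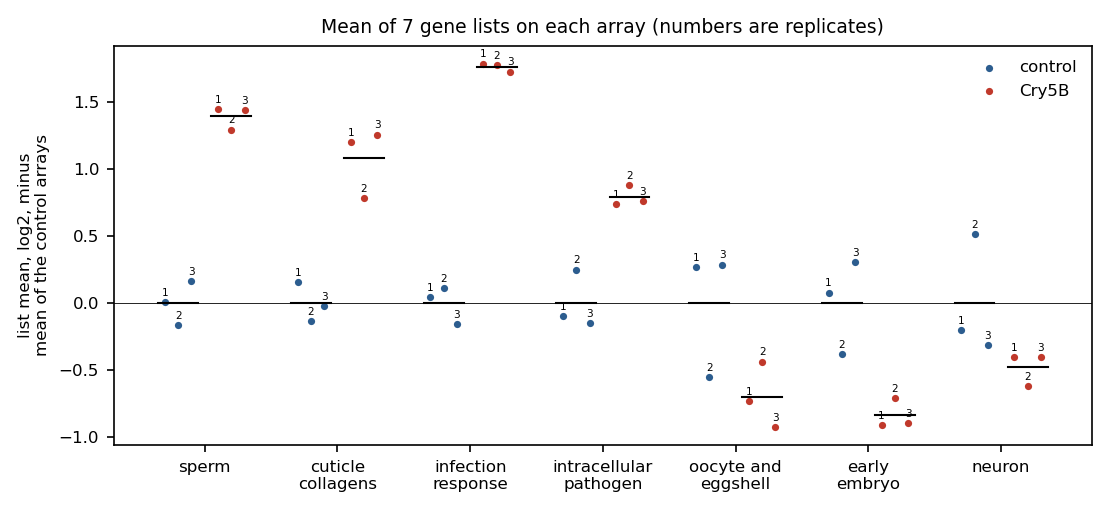
Mean of 7 gene lists on each array, on the log2 scale and relative to the mean of the control arrays (vertical axis), for control (blue) and Cry5B (red), with replicate numbers beside the points and black bars for group means. Red points lie above all blue points for sperm, collagen, infection response and intracellular pathogen genes and below them for embryo and neuron genes. Control replicate 2 lies apart from the other control arrays for oocyte and eggshell, embryo and neuron genes. After muscle and neuron centring the medians of the oocyte and neuron lists are 0.01 and 0.17.

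Neuron markers lay lower in Cry5B worms by the median. By sign 29 members lay below 0 and 9 above it, the latter including egl-3, flp-1, flp-9 and nlp-21 (named after their values were seen). Of 38 measured, 9 fell, none rose and 29 did not pass (16 and 0 adjusted over the list alone), with a median 1.5-fold lower (-0.58; camera adjusted p = 0.000257, and adjusted p = 0.576 with an estimated correlation). The intraflagellar transport gene osm-6 fell 2.64-fold (-1.40 ± 0.27, adjusted p = 0.015) and unc-86, a transcription factor of neuronal identity, 2.61-fold (-1.39 ± 0.19, adjusted p = 0.0037). Pharynx markers rose in 1 and fell in 4 of 17 cases, also adjusted over the list alone (median -0.49; camera adjusted p = 0.0176, and adjusted p = 0.576 with an estimated correlation). The gland gene phat-5 fell 5.25-fold (-2.39 ± 0.29, adjusted p = 0.0019) and the transcription cofactor gene eya-1 2.88-fold (-1.53 ± 0.20, adjusted p = 0.0028). The neuron list had 16 falls and 4 rises with a median of -0.35 without control replicate 2, and the pharynx list a median of -0.13 and camera adjusted p = 0.235. Camera did not call the pharynx list without Cry5B replicate 2 either (0.169). Falls among neuron markers numbered 2, 3, 3, 4 and 5 without Cry5B replicates 1, 2 and 3 and control replicates 1 and 3. The gene osm-6 was not called without any 1 of the Cry5B arrays or control replicate 3 (adjusted p 0.054 to 0.082). Muscle and neuron centring, which uses these markers, ended the calls of osm-6, unc-86 and eya-1 and turned the medians to 0.17 and 0.26. The neuron list then had 3 rises and no fall, and after levelling on muscle and neuron genes 2 rises and 1 fall, against 20 falls after ribosomal centring. The pharynx list had 1 rise and 1 fall, 1 and 2, and 0 and 6 under these 3 scalings.

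Markers of the intestine, body wall muscle and epidermis were not called as sets. In the intestine list of 18, 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0753). The lectin gene clec-63 rose 2.65-fold (1.40 ± 0.26, adjusted p = 0.013), the aquaporin gene aqp-8 rose 2.42-fold (1.28 ± 0.25, adjusted p = 0.016), and the metallothionein gene mtl-2 fell (-1.16 ± 0.29, named after its values were seen). In the muscle list 1 of 21 fell, hlh-1, the MyoD homologue, by 1.55-fold (-0.64 ± 0.15, adjusted p = 0.037), and none passed adjusted over the list alone (camera adjusted p = 0.445). The myosin chaperone gene unc-45 had a change of -0.58 ± 0.18 (adjusted p = 0.082). In the epidermis list of 16, 2 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.684). The lipid transporter gene tat-2 rose 4.37-fold (2.13 ± 0.32, adjusted p = 0.0051) and the engrailed homologue ceh-16 fell 3.20-fold (-1.68 ± 0.25, adjusted p = 0.0054). The medians were 0.24, -0.03 and 0.05, of which ribosomal centring turned those of intestine and epidermis to -0.16 and -0.36 and muscle and neuron centring that of muscle to 0.72. Rises and falls were 1 and 2, 0 and 3, and 1 and 4 after ribosomal centring, and 4 and 0, 0 and 0, and 2 and 0 after muscle and neuron centring. The epidermis list's mean of -0.08 and camera direction (lower) were opposite to its median. Leaving out control replicate 2, 8 intestine markers rose and camera called the list (adjusted p = 0.000461). The gene clec-63 was not called without Cry5B replicate 1 or 3 (0.072 and 0.071), aqp-8 without any 1 of the Cry5B arrays or control replicate 1 (0.053 to 0.081) and hlh-1 without any 1 of the Cry5B arrays or control replicate 3 (0.091 to 0.15). Scaling ended the calls of aqp-8 (ribosomal centring), ceh-16 and hlh-1 (muscle and neuron centring, with hlh-1 at 0.11).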

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

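The fit to listed probe sets, the levelling on muscle and neuron genes and the setting without both arrays numbered 2 were chosen only after the data were seen. The count of 3294 called genes stayed within 1.5 times under cyclic loess (3354), ribosomal centring (4644), muscle and neuron centring (2904), levelling on those genes (3112), the filter on dim probe sets (3378), trend and robust moderation (3283), a fold of at least 2 (2518), the mean over probe sets (3294) and listed probe sets (3379). The count was 1163 without variance moderation, 7773 with array weights and 6721 without both arrays numbered 2, and 1587 to 5878 with 1 array left out (fewest without Cry5B replicate 1, most without control replicate 2). In none of the 19 settings run was a called gene called in the opposite direction. The replicate numbers did not pair the arrays (r of deviations for the same number -0.003, -0.082 and -0.098); with the replicate block 2478 genes were called, 2387 of them shared, no list changed its call, and of the named genes ifa-4, lin-41, vit-2, vit-5, ptr-22 and hlh-1 no longer passed. Camera's adjusted p for each list was on the same side of the threshold, in the same direction, without dim genes and with a background free of stage genes. With an estimated correlation 17 lists lost their call: C-type lectins, epidermal peptides, intracellular pathogen response, major sperm proteins and adult cuticle 0.251 each, lysozymes 0.434, unfolded protein response 0.516, xenobiotic enzymes, ribosomal proteins, vitellogenins and early embryo 0.430 each, sperm genes 0.139, oocyte 0.526, germ cells 0.75, collagens 0.346, pharynx and neuron 0.576 each. Correlated members alone need not account for them, since camera's p also rose where the estimate was no higher. The C-type lectins' estimated correlation, 0.014, lay near the preset 0.01. For infection response genes (-0.0026) and antioxidant enzymes (-0.029) the estimate lay below it. Camera's adjusted p still rose, from 2.97e-16 to 0.0182 and from 0.105 to 0.355. An estimated correlation also makes camera take p from the residual degrees of freedom of the 6 arrays, rather than from a number near that of the genes. The share of each loss that this gives was not tested. Under cyclic loess antioxidant enzymes passed at 0.0372. Without both arrays numbered 2, toxin defence (0.00972), fasting and lipids (0.0366), moulting (0.000296) and intestine (0.000939) passed, the unfolded protein response (0.0542), pharynx (0.991) and neurons (0.0754) did not, and the directions of muscle (0.0792) and epidermis (0.237) were reversed; the cause was not tested. With 1 array left out, camera's adjusted p ranged from 0.173 to 0.902 for muscle and 0.354 to 0.841 for epidermis, both with a reversal, 0.0413 to 0.856 for intermediate filaments, with a reversal, 0.0144 to 0.300 for toxin defence, 0.00758 to 0.451 for fasting and lipids, 0.031 to 0.144 for hypoxia, 0.000461 to 0.346 for intestine, 0.00844 to 0.764 for moulting, 2.04e-05 to 0.297 for germ cells and 0.00262 to 0.235 for pharynx. Ribosomal centring reversed ifa-1 (-0.34), ifb-1 (-0.36), ifb-2 (-0.076) and ifp-1 (-0.39), and muscle and neuron centring reversed ifd-1 (0.33), lmn-1 (0.55), lin-41 (0.041), vit-5 (0.078), hlh-1 (0.11), unc-45 (0.17) and pmk-1 (0.64), because each centring adds one shift to all genes. With 1 array left out, changes ranged from -0.15 to 0.29 for ifa-1, -0.13 to 0.22 for ifb-1, -0.73 to 0.081 for ifd-1, -0.23 to 0.39 for ifp-1 and -0.31 to 0.10 for pmk-1. Of 83 named genes, 80 had the same call and direction under cyclic loess, 3 others passing there, and 83 when probe sets were averaged. Signal over background was not analysed, since no background value or detection p was used here.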

Other observations

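After the data were seen, genes were grouped by the stem of their symbol, and 173 stems with at least 10 measured genes, fixed lists included, were tested for an excess of called rises or falls over all genes. The tests were one-sided Fisher's exact tests (346 tests, Benjamini-Hochberg adjusted), which treat genes as independent. Of 26 stems past 0.05, the 19 with under 50% of their members in the fixed lists are given here. Members in the lists numbered 25 for unc, 4 for ceh, 3 for egl, 3 for skr, 2 for hlh and 0 for the others. An excess of falls was found for fbxb (39 of 108 genes, no rise), fbxc (12 of 44, 2 rises), ceh (25 of 64, 1 rise), unc (17 of 91), cutl (10 of 28), hlh (9 of 25), inx (6 of 21), egl (6 of 26), dyf (4 of 12), vab (4 of 10), lido (5 of 17, 1 rise) and skr (5 of 20, 3 rises). An excess of rises was found for fbxa (39 of 188, 5 falls), ttr (16 of 58, 3 falls), clc (12 of 30, 3 falls), nep (12 of 26, 1 fall), nspg (7 of 14, 1 fall), snf (5 of 11, 1 fall) and hrg (5 of 13). On camera with an estimated correlation, adjusted over the stems, 0 of the 19 passed (smallest adjusted p 0.650). The counts also depend on the scaling. After muscle and neuron centring 1 gene each of fbxb, hlh and egl fell and none of the other 9 stems with falls. After ribosomal centring rises and falls were 25 and 16 for fbxa, 8 and 3 for ttr, 10 and 6 for clc, 5 and 1 for nep, 2 and 1 for nspg, 3 and 2 for snf and 1 and 0 for hrg. After levelling on muscle and neuron genes, a smaller shift, falls numbered 11 for fbxb, 6 for ceh, 5 for unc, 4 each for cutl, dyf and skr, 2 each for fbxc and hlh, 1 each for egl and vab and 0 for inx and lido. Without control replicate 2, falls numbered 73 for fbxb, 28 for unc, 18 for fbxc, 10 for lido, 10 for skr, 9 for egl and 7 for cutl, and fbxa had 60 rises and 16 falls.

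Of the tests that follow, 2 were chosen only after the result was seen: that of the third larval stage and that of control replicate 2. Repeats of the shares with 1 array left out, levelling on muscle and neuron genes and the limits put on the normalization tests were not set in advance either. Other splits of the 6 arrays were counted as well: the real split called 3294 genes, the highest of the others called 0, and 1 of the 10 splits gave as many as the real one. With 10 splits a share under 0.05 cannot be reached. Each of the other splits mixes Cry5B and control arrays, so a difference between the real groups widens the spread within its sets and lowers its calls. A low count there says little about false calls.

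Infection response genes rose by a median of 1.95 on the log2 scale. The lowest median of these genes over cyclic loess and both centrings was 1.54, so none of these scalings ended the rise. Each starts from the RMA values and cannot undo quantile normalization, so whether it contributed stays open. A difference in developmental stage may contribute and cannot be told apart from the toxin: the slope within groups on a stage score (sperm minus early embryo mean) gave a share of 33.4% of the rise, with a 95% interval from -70.8% to 138% on 3 residual degrees of freedom and, with 1 array left out, an upper limit from 79.9% (without control replicate 3) to 258% (without Cry5B replicate 2). An effect of the toxin itself stays open and is untested, because every Cry5B array carries another stage label than the control arrays.

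Of the sperm genes 28 of 46 rose, of the cuticle collagens 48 of 167 rose and 7 fell, and of the early embryo genes 16 of 52 fell and 1 rose, with camera adjusted p of 0.139, 0.346 and 0.430 under an estimated correlation. A single array did not carry the medians, since the smallest absolute median of the 3 lists with any array left out was 0.479. Collection of the Cry5B worms at the third larval stage, before sperm genes are expressed, is argued against by the median of the sperm genes, which lay 1.18 above the control worms. Vitellogenin and oocyte genes, mostly expressed after that stage, averaged 11.39 and 10.3 in Cry5B worms, values read after the data were seen. Both means lay above the upper quartile of every Cry5B array, at most 7.43, and argue against that stage too. Against control worms both means were lower, with differences of -1.07 and -0.699. Which later stages were collected stays open, and an effect of the toxin on the sperm, collagen and embryo genes is untested.

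Neuron markers lay lower by a median of -0.58. Quantile normalization as the cause stays open: the highest median over cyclic loess and ribosomal centring was -0.47, but neither could raise it by much (a limit on this test added after its result was seen), while muscle and neuron centring, which uses these markers and overshoots, turned it to 0.17 and levelling on the same genes left -0.19. Fewer embryos inside the Cry5B worms could lower them: of the 38 markers and the 52 embryo genes none was in another list, and the within-group slope gave a share of -220% (95% interval -301% to -138%), opposite to that explanation. Without control replicate 2 the upper limit was 58.7%, above the bound of 50% set in advance, so the evidence against it rests on 1 array and the explanation stays open; this repeat was added after the result was seen. Control replicate 2, whose neuron mean was 8.38 against 7.66 and 7.55 on the other control arrays, may carry part of the difference: without it the median was -0.35, which neither ends the shift nor leaves it whole, and an effect of the toxin on neurons is untested.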
